A study of Homo sapiens with 14 samples.

How the data were processed

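The samples were differentiated Caco-2 cells on 2-colour arrays of 19200 probes, 14 arrays in all. Per the labels, the sample RNA carried Cy5 and a common reference of undifferentiated, untreated cells carried Cy3 on every array, so no dye was swapped. The authors' values come as 1 table of log2 ratios; the deposited table states neither its base nor its direction nor its centring, and base 2 is assumed. The largest size among the values is 7.43, which as a base 10 logarithm would be a ratio beyond the range of a scanner. The mean of each array over all its values lay within 0.00476 of 0, as in values centred on the array mean. The software and normalization used to make the values are not given in the sources used here. The median of an array over all its values ranged from -0.09 to 0.21. Scanner intensities were not analysed here.

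Gene names come from the platform annotation paired with the table: 13720 probes had 1 gene symbol, 445 several and 5035 none. Symbols were checked through their Entrez identifiers against NCBI RefSeq annotation of GRCh38.p14, where 13555 matched. No gene was named from a probe with several symbols.

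Groups were taken from the labels. The rows fall into 48 print blocks of 400, and 50 positions are unnamed in every block. These 2400 spots were treated as control spots and left out, a choice made after the layout was seen, since no row is named as a control; counts with them kept stand in the closing section. No column of per-sample values was left unmapped. A probe was tested if it had at least 3 values in each group of 4 arrays and both values at dose 1000. That left 3611 probes, with 1.28% of values missing, of which 421 had no symbol and 64 several. Values were used as deposited, because the array medians over all values spanned less than 0.5; over gene probes measured on all arrays they span 0.56, from -0.13 to 0.43, so counts after centring are given beside the main ones.

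All 14 arrays entered 1 linear model in limma 3.58.1 under R 4.3.3 (lmFit, contrasts and eBayes), and p-values were adjusted by Benjamini-Hochberg at 0.05 within each comparison. The comparisons were each dose against the control, each pair of doses, and a slope over dose steps coded 0, 1, 2 and 3. Adjusted p-values printed for named genes come from this probe fit. Gene lists were tested at gene level, on the mean of a gene's probes, with missing values filled by the gene's group mean for the list test only. camera was run with a preset correlation of 0.01 and again with an estimated correlation. The calls that hold with an estimated correlation are the immediate-early list at dose 1000 and none at the other doses. Values of list members come from the gene-level fit. 37 lists were fixed before the data were examined, and 30 had at least 5 measured genes. The other 7 were too small among the probes tested: interferon response (2 measured genes), secretory lineage (0), mucins and antimicrobial peptides (2), bile acid signalling (2), carbonic anhydrases (3), histones (4), and markers of lymphocytes, macrophages and fibroblasts (1).

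Named genes follow a rule fixed before the data were examined. For each dose against the control it takes, among called probes with 1 symbol whose arrays at that dose all lie on one side of the control mean, the 10 largest rises and 10 largest falls, or the 5 lowest p where none is called. For other comparisons it takes 5 of each, with the higher dose set against the lower in the same way, and it adds up to 4 called members per list, or the 2 with the lowest p.

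The fits were tested on simulated data with the real means, spreads and missing values of 3611 probes and independent noise, with 200 probes changed in each of 20 draws. For dose 1000 against the control, 47.8% of changes of 1 on the log2 scale and 91.4% of changes of 2 were recovered. For dose 100 the shares were 65.6% and 95.7%, and for dose 10 they were 66.4% and 96.3%. Of the calls, 4.53% were false at dose 1000, 4.60% at dose 100 and 5.20% at dose 10. For the slope, 86.0% of probes with a slope of 0.5 per step were recovered. A list raised by 1 at dose 1000 was found in 100% of draws, with 0 of 580 other lists called. As the simulated noise was independent between probes, this says nothing of false calls for lists whose genes vary together.

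Alternatives fixed in advance covered array centring, quantile normalization, scaling of arrays to 1 median absolute log ratio, missing values, array weights, robust eBayes, the arrays fitted, a minimum fold change, a variance filter, the dose scale, the replicate number as a block and each array left out. Added after seeing the data were fits with the repeated spots kept, without the 3 arrays that stand apart, with these arrays as a batch term, with the shift of the repeated spots as a covariate, and with named probes only. Figures were drawn with matplotlib 3.10.9.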

Results

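Gene expression was measured in differentiated Caco-2 cells, a human colon adenocarcinoma line that takes on features of small intestinal enterocytes in culture. The cells had been differentiated for 18 days and were then kept for 10 h without bacteria (control) or with Lactobacillus plantarum, a lactic acid bacterium found in fermented foods and in the gut, at doses labelled 10, 100 and 1000 with no unit. There were 4 arrays each for the control, dose 10 and dose 100, and 2 for dose 1000. Each array set sample RNA (Cy5) against a common reference of undifferentiated, untreated Caco-2 RNA (Cy3), and the deposited values are log ratios. The question is how the expression of an intestinal epithelial cell depends on the dose of the bacterium. An array held a value for 5064 to 8521 of 19200 probes, and 3611 gene probes had enough values to be tested. Of these, 3126 carried 1 gene symbol and stood for 3038 genes. The number of arrays limits the precision, and nothing in the labels says that arrays of a group came from separate cultures, so p-values measure the spread between these arrays.

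In the control cells, enterocyte genes lay above the undifferentiated reference and cell cycle genes below it. All 11 measured genes of the enterocyte list had a mean ratio above 0, with a median of 2.65 on the log2 scale. They included the brush border enzyme gene ALPI (3.17 ± 0.29, SD, n = 4) and MYO1A, which encodes a brush border myosin (3.02 ± 0.14, SD, n = 4). Of 23 cell cycle genes, 21 lay below 0, with a median of -1.12, CCNB1 at -2.38 ± 0.29 and BIRC5 at -2.15 ± 0.21 (SD, n = 4). The direction of the ratio is not stated in the sources used here, and these markers are the basis for reading it as sample over reference. The base of the logarithm is not stated either and was taken as 2; if it were natural, each log2 value would be 1.44 times as large.

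3 arrays stood apart from the rest: dose 10 replicates 2 and 4 and dose 100 replicate 3. Over 1020 unnamed spots with a value on every array, at positions unnamed in every print block, their median shift from the controls was between -1.79 and -1.60, against -0.61 to 0.30 in the other 11 arrays. Over gene probes they correlated with the controls at 0.646 to 0.751, while the other dose 10 and dose 100 arrays correlated with them at 0.784 to 0.932. The dose 1000 arrays correlated with the controls at 0.606 to 0.651, and both ends of the shift range of the 11 arrays were theirs. Dose 1000 replicate 2 correlated with the 3 arrays at 0.736, 0.692 and 0.743, about as with replicate 1 (0.725). With dose 10 replicates 1 and 3 it correlated at 0.665 and 0.687, and with dose 100 replicates 1, 2 and 4 at 0.765, 0.731 and 0.623. Dose 1000 replicate 1 correlated with the 3 at 0.468, 0.422 and 0.504. These correlations run across 3065 probes of an array pair, which are not independent replicates.

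**Figure D1:**
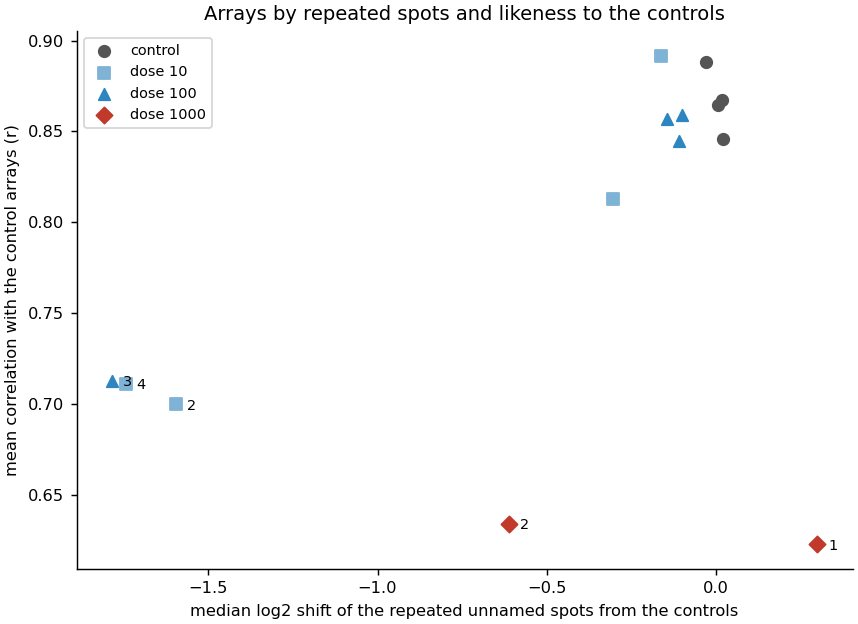
Each point is 1 array. The x axis is the median log2 shift of the repeated unnamed spots from the control arrays, and the y axis is the mean Pearson correlation with the control arrays over gene probes. Dose 10 replicates 2 and 4 and dose 100 replicate 3 sit at shifts of -1.60, -1.74 and -1.79, and both dose 1000 arrays lie lowest on the y axis, at 0.623 and 0.634.

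At dose 1000, CYP1A1, JUNB, ZFP36 and NFKBIA were among the genes that rose, and HSP90AA1 was among those that fell. CYP1A1, the aryl hydrocarbon receptor target that oxidises polycyclic compounds, rose 6.12-fold, from a log2 ratio of 2.13 ± 0.04 (SD, n = 4) in the control to 4.74 ± 1.09 (SD, n = 2). JUNB, a subunit of the AP-1 transcription factor, rose 5.97-fold, from -0.23 ± 0.23 to 2.34 ± 0.32. ZFP36, which promotes decay of AU-rich mRNAs, rose 4.27-fold and NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, rose 4.15-fold. HSP90AA1, a cytosolic chaperone, fell by 2.55 on the log2 scale, from -0.20 ± 0.24 to -2.75 ± 2.17, with its 2 dose 1000 arrays far apart.

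In all, 484 of 3611 probes were called by limma at an adjusted p below 0.05 against the control, 152 higher and 332 lower. The called probes with 1 symbol covered 413 genes. Centring each array on its median over gene probes gave 579 calls, 252 higher and 327 lower, so the share of rises went from 31.4% to 43.5%. Centring took a median shift of -0.07 out of this comparison, -0.15 out of dose 1000 against dose 100, -0.20 out of dose 1000 against dose 10 and 0.13 out of dose 10 against the control. It turned the direction of no called gene named here. Without dose 1000 replicate 1 the count was 133, of which 115 were among the 484, with 45 higher and 88 lower, and the remaining lone array was then taken to vary like the other groups. The rises were fewer without dose 1000 replicate 2 (94, beside 386 falls), control replicate 1 (94, beside 253) and control replicate 2 (75, beside 253). Without the 3 arrays that stood apart the count was 739, 294 higher and 445 lower, and included all 484.

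Among the 10 largest rises, MICAL2, which encodes an actin-oxidising enzyme, had the largest (log2 fold change 3.03, SE 0.63, adjusted p = 0.00755), with its dose 1000 arrays far apart (-0.26 ± 2.00, SD, n = 2). The creatine transporter gene SLC6A8 (2.34, SE 0.57, adjusted p = 0.0149) and SLC6A10P (2.82, SE 0.57, adjusted p = 0.00612) are near-identical copies, and which of them the signal comes from is uncertain. DGAT1, the last enzyme of triglyceride synthesis, rose by 2.23 (SE 0.40, adjusted p = 0.00340) and APOC3, an apolipoprotein, by 2.11 (SE 0.62, adjusted p = 0.0350). TNFAIP3, a ubiquitin-editing inhibitor of NF-kB signalling, rose by 1.85 (SE 0.52, adjusted p = 0.0313). The adjusted p was 0.000104 for JUNB, 0.000715 for CYP1A1, 0.000782 for ZFP36 and 0.00139 for NFKBIA.

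The 10 largest falls held 4 zinc finger genes and 2 genes of the NBPF family. ZNF117 (-2.99, SE 0.36), ZNF43 (-2.81, SE 0.46), ZNF93 (-2.76, SE 0.49) and ZNF257 (-2.69, SE 0.37) fell with adjusted p from 0.000437 to 0.00306. NBPF12 (-2.89, SE 0.29) and NBPF10 (-2.63, SE 0.27) fell with adjusted p = 0.000104 each. Members of both families are closely alike in sequence, so which gene each probe reports is uncertain. The other falls were IPO7, a nuclear import receptor (-2.69, SE 0.56, adjusted p = 0.00660), HSP90AA1 (-2.55, SE 0.65, adjusted p = 0.0190), CFHR4 (-2.42, SE 0.25, adjusted p = 0.000104) and PDCD4, an inhibitor of translation initiation (-2.40, SE 0.36, adjusted p = 0.00157). Of the 20 genes named by this rule, the call was lost without dose 1000 replicate 1 for SLC6A10P, SLC6A8, APOC3, IPO7 and HSP90AA1, and without dose 1000 replicate 2 for MICAL2, SLC6A8, APOC3 and TNFAIP3. The calls of APOC3 and TNFAIP3 were also lost without any 1 of the 4 control arrays.

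**Figure D2:**
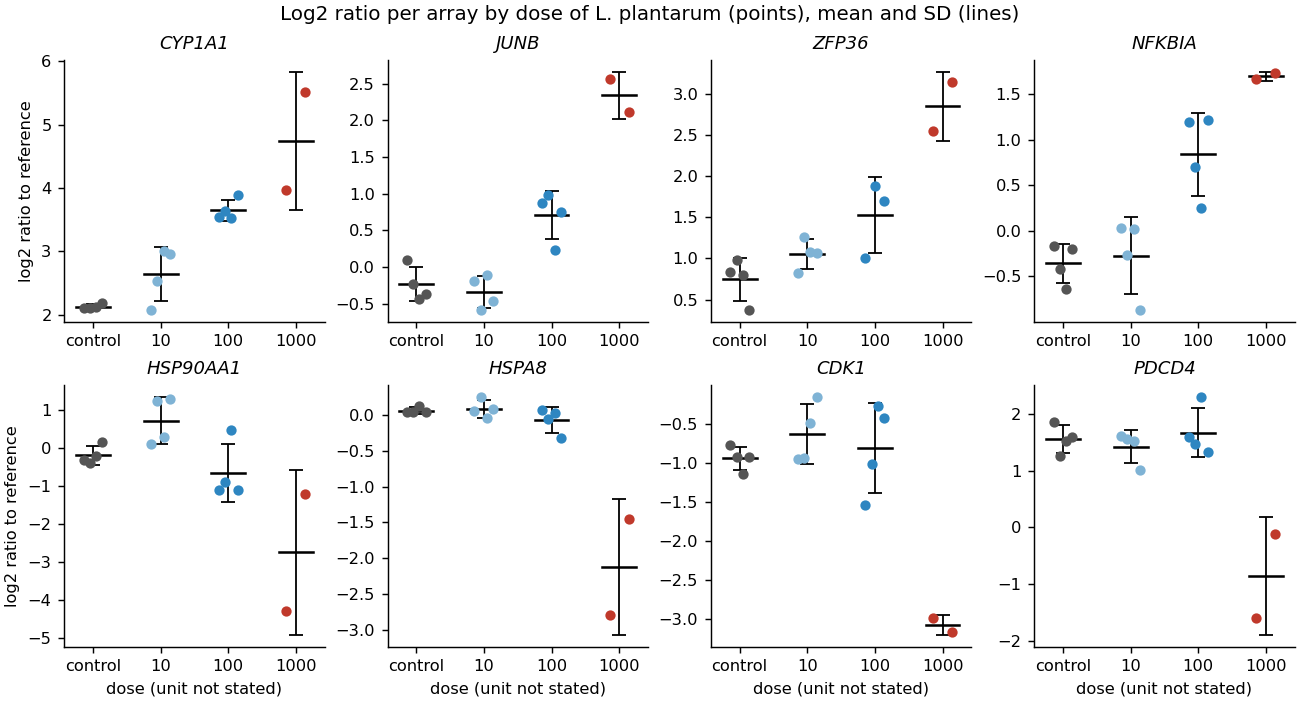
Each panel shows 1 gene; points are arrays, the horizontal line is the group mean and the bars are the SD. The x axis is the group, with doses in a unit that is not stated, and the y axis is the log2 ratio to the undifferentiated reference, scaled per gene. CYP1A1 stood at a mean of 2.13 in the control and 4.74 at dose 1000, and PDCD4 at 1.56 and -0.85.

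The immediate-early list and the list of NF-kB targets, cytokines and chemokines shifted upward at dose 1000, among the members that could be tested. These were 10 of 28 immediate-early genes on the array and 7 of 35 NF-kB genes. Probes of KLF4, DUSP2 and CCN1 of the first list and of IL1B and TNFAIP2 of the second dropped out. They had a value on all controls and on neither dose 1000 array, and a missing value is not a low one. Of 10 immediate-early genes measured, 4 rose over all genes tested, and 6 when adjusted over the list alone: JUNB, ZFP36, IER3 (1.72, SE 0.30) and KLF6 (1.30, SE 0.32) passed over all genes, and KLF6 had adjusted p = 0.216 without dose 1000 replicate 1. The list had a median log2 fold change of 1.06 and an adjusted p of 0.00128 (camera, 30 lists), and adjusted p = 0.0484 with an estimated correlation. Of 7 NF-kB genes, 5 rose over all genes, and adjusted over the list alone 5 were higher and 1 lower. They included the NF-kB inhibitor NFKBIA, BCL3, a nuclear IkB protein (1.58, SE 0.24), and the cytokine gene IL32 (1.43, SE 0.38), which had adjusted p = 0.169 without dose 1000 replicate 2 and 0.0523 without replicate 1. The list's median was 1.43 and its adjusted p 0.00939, with adjusted p = 0.604 with an estimated correlation. Without dose 1000 replicate 2 the adjusted p of the NF-kB list was 0.0569, and without replicate 1 the number of shifted lists was 4. With only the probes measured on all 14 arrays the immediate-early list had adjusted p = 0.102, and the NF-kB list was not tested. The estimated correlation aside, the range over alternatives was 0.000208 to 0.113 for the immediate-early list and, over 1 alternative fewer, 0.00357 to 0.0569 for the NF-kB list. With 1 value required in each group the immediate-early list had the 0.113, and the interferon response list and the markers of other cell types, which otherwise had too few genes, were then higher with the NF-kB list (each 0.0209).

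Of 8 heat shock genes, 3 fell over all genes and 3 adjusted over the list alone: HSP90AA1, HSPA8, the constitutive Hsc70 (-2.19, SE 0.28), and its co-chaperone DNAJA1 (-1.56, SE 0.34). The list did not pass, with a median of -0.70 and adjusted p = 0.0529, and adjusted p = 0.998 with an estimated correlation. Over the alternatives other than the estimated correlation the adjusted p ranged from 0.00890, without dose 1000 replicate 2, to 0.184, with 21 of 29 settings over the threshold. The others below it were array centring (0.0238), quantile normalization (0.0313), array weights (0.0237), the 3 arrays as a batch term (0.0313), the shift of the repeated spots as a covariate (0.0131) and the fits without control replicate 1 (0.0470) or 2 (0.0460). In the endoplasmic reticulum, HSP90B1 (-1.50, SE 0.45) and DNAJB11 (-1.07, SE 0.26) fell while PPP1R15A, which directs dephosphorylation of eIF2alpha, rose (1.42, SE 0.26), the 3 called of 13 genes in the unfolded protein response list, where 1 was higher and 3 lower adjusted over the list alone. Without dose 1000 replicate 1 the adjusted p was 0.280 for HSP90AA1, 0.101 for DNAJA1, 0.513 for HSP90B1 and 0.192 for DNAJB11, while HSPA8 and PPP1R15A passed without any 1 array.

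Genes of proliferation and of lipid and drug handling were called in both directions, with no shift of their lists. Of 20 cell cycle genes, 4 fell and 1 rose, both over all genes and adjusted over the list alone. CDK1, the kinase that drives mitosis (-2.13, SE 0.32), and RRM2, a subunit of ribonucleotide reductase (-1.73, SE 0.27), fell, while CCNE1, the G1 cyclin E, rose by 0.96 (SE 0.27). The list's adjusted p was 0.492. CDK1 and RRM2 passed without any 1 array, and CCNE1 had adjusted p = 0.125 without dose 1000 replicate 2 and 0.105 without replicate 1. Of 13 cholesterol synthesis genes, SC5D (-1.36, SE 0.32), SQLE (-1.04, SE 0.28) and LSS (-0.73, SE 0.20) fell and PMVK rose (1.29, SE 0.28), and adjusted over the list alone 3 were higher and 4 lower. The list's median was -0.22 while its test pointed up, with an adjusted p of 0.972. Among 6 xenobiotic genes, CYP1A1 rose and the efflux pump gene ABCB1 fell (-1.20, SE 0.28), over all genes and adjusted over the list alone, with a list adjusted p of 0.819. ABCC2, another efflux pump (-1.51, SE 0.35), and CAT, catalase (-1.01, SE 0.30), fell in the oxidative stress list of 12 genes, where GPX4 rose (1.16, SE 0.35), the list's adjusted p was 0.996, and 3 were higher and 4 lower adjusted over the list alone. Without dose 1000 replicate 1 the adjusted p ranged from 0.0937 for LSS to 0.315 for CAT among the cholesterol, efflux pump and oxidative stress genes named here.

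Single genes of the other lists were called too, and the lists not named above had adjusted p from 0.492 to 0.972. ACADS, a short-chain fatty acid dehydrogenase, rose (1.74, SE 0.35), while ACSL1, which activates long-chain fatty acids, fell (-1.21, SE 0.25). MT2A, a metallothionein, rose (1.54, SE 0.24) and SLC40A1, the iron exporter ferroportin, fell (-1.71, SE 0.33). In the transporter list the chloride channel gene CFTR fell (-1.72, SE 0.33). The tight junction gene CLDN1 (-1.61, SE 0.31) and PALS1, a polarity protein (-1.01, SE 0.28), fell out of 6 measured. ADM (1.22, SE 0.24) and EGLN3 (0.77, SE 0.24) rose and KDM3A (-1.37, SE 0.32) and P4HA1 (-1.15, SE 0.34) fell among 8 hypoxia targets. GDF15, a stress-induced cytokine, rose (1.20, SE 0.24), and RPL22 was the only one called of 31 ribosomal protein genes (-1.33, SE 0.25). Adjusted over the list alone, 2 tight junction genes and 2 hypoxia targets were lower and 2 hypoxia targets higher, as over all genes. The counts that follow cover only the called members taken by the naming rule, up to 4 per list with the largest change. Of 50 list members called at this dose, 14 passed without any 1 array, among them MT2A, CFTR and ADM, and 35 did not pass without dose 1000 replicate 1, 10 without dose 1000 replicate 2 and 19 without at least 1 control. In this group the adjusted p without dose 1000 replicate 1 was 0.0523 for ACADS and ACSL1, 0.0761 for SLC40A1, 0.0872 for CLDN1, 0.183 for PALS1, 0.201 for KDM3A, 0.365 for P4HA1, 0.0539 for GDF15 and 0.0666 for RPL22, and EGLN3 had 0.253 without replicate 2.

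**Figure D3:**
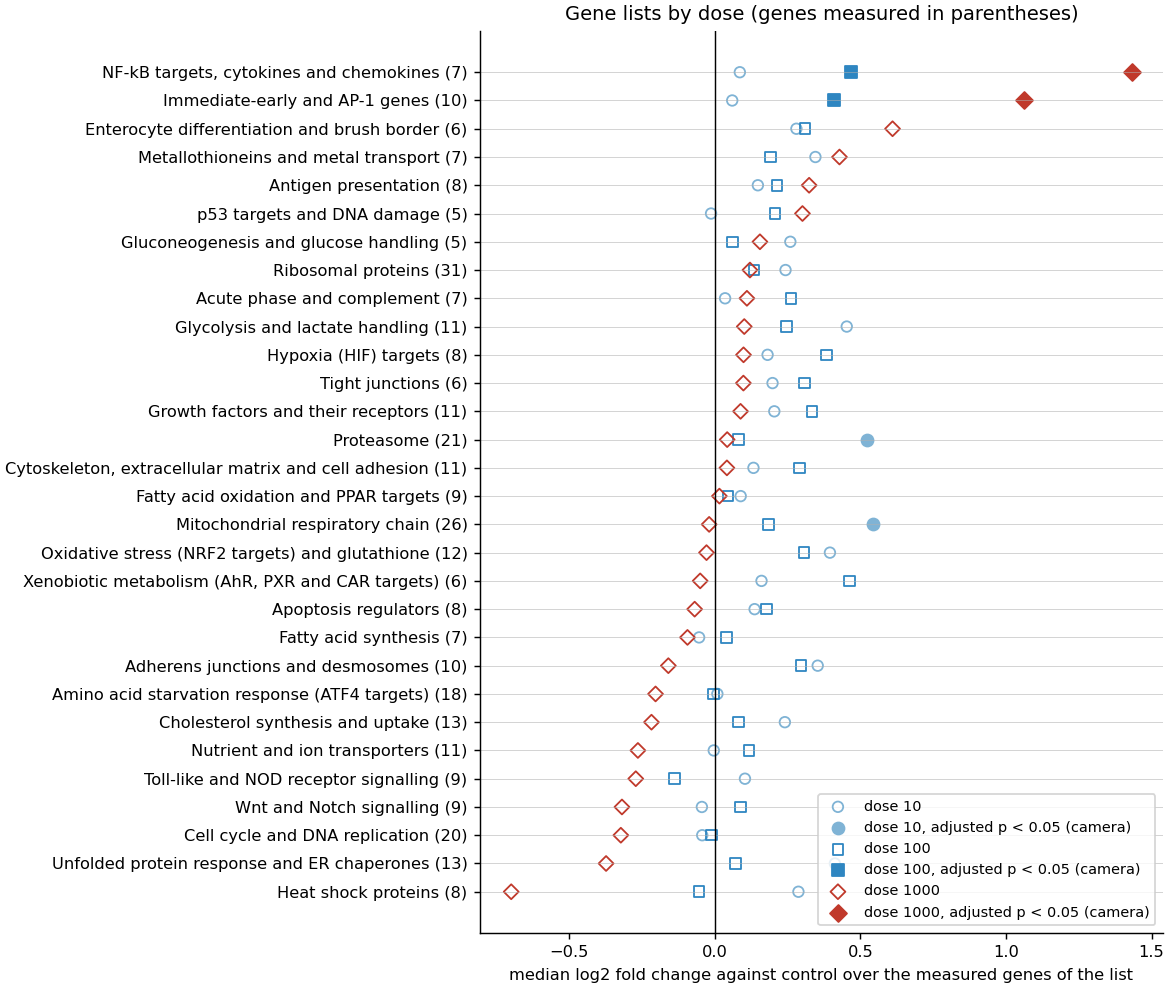
Each row is a gene list fixed in advance, with the number of measured genes in parentheses. The x axis is the median log2 fold change against the control over those genes, at each dose, and filled symbols mark camera calls. The NF-kB and immediate-early lists lie at 1.43 and 1.06 at dose 1000, and the heat shock list at -0.70.

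At dose 100 no single gene passed against the control. The lowest p-values belonged to CYP1A1 (log2 fold change 1.52, SE 0.28), NFKBIA (1.20, SE 0.25), AMOTL2 (0.89, SE 0.19), GRB7 (0.79, SE 0.17) and JUNB (0.94, SE 0.20), with adjusted p from 0.247 to 0.248. CYP1A1 had a ratio of 3.65 ± 0.17 (SD, n = 4) against 2.13 ± 0.04 in the control, and all 4 arrays at this dose lay above all controls. limma called 0 of 3611 probes, and 254 had an unadjusted p below 0.05. When only the control and dose 100 arrays were fitted, 4 probes were called, and array quality weights gave 51. CYP1A1 was the single call without dose 1000 replicate 1 and without dose 1000 replicate 2.

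2 lists were nevertheless shifted upward at dose 100, the same pair as at dose 1000. The immediate-early list had a median of 0.41 and an adjusted p of 0.00152, and adjusted p = 0.0518 with an estimated correlation. 0 of its 10 genes passed over all genes and 3 rose when adjusted over the list alone, among them JUNB and DUSP6, a phosphatase of ERK (1.38, SE 0.34). The NF-kB list had a median of 0.47 and an adjusted p of 0.00674, and adjusted p = 0.454 with an estimated correlation. 0 of its 7 genes passed over all genes and 3 rose adjusted over the list alone, among them NFKBIA and TNFAIP3 (1.59, SE 0.42). The call of the NF-kB list was lost without dose 100 replicate 1 (adjusted p = 0.0568) and without dose 100 replicate 4 (adjusted p = 0.125). Without the 3 arrays that stood apart, the immediate-early list had adjusted p = 0.000470, and the xenobiotic list, at 0.0579 with all arrays, had adjusted p = 0.00305. Over the alternatives other than the estimated correlation the immediate-early list ranged from 0.000109 to 0.0646 and the NF-kB list from 7.93e-06 to 0.125. In the xenobiotic list 0 of 6 genes passed over all genes and 2 rose adjusted over the list alone, CYP1A1 and UGT1A6, a glucuronosyltransferase (0.71, SE 0.22). The number of shifted lists was 4 without control replicate 2, dose 10 replicate 1 or dose 100 replicate 3, 1 without dose 100 replicate 1 or 4, and 5 without either dose 1000 array.

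Among the dose 1000 calls, 72.9% of probes had the same sign at dose 100, 89.5% of the rises and 65.4% of the falls. Both comparisons share the control arrays, and unchanged groups simulated against those controls gave 79.1% among as many top probes. Those probes were picked from noise alone, while the calls had a median absolute log2 fold change of 1.11. The 79.1% is therefore not the share to expect of the calls. With different controls for each dose, where 147 to 249 probes were called at dose 1000, the share was 65.5% of those, from 59.6% to 73.2% over 6 ways of parting them. Across all probes the fold changes of the 2 doses correlated at 0.418, against 0.409 in simulations and 0.262 with different controls. Their covariance was 0.0842, against 0.0420 in simulations and 0.0605 with different controls.

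At dose 10 no single gene passed either. The lowest p-values were those of MDK, the growth factor midkine (log2 fold change 1.21, SE 0.30), RPL7AP10 (1.79, SE 0.45), DDX39B, an RNA helicase of mRNA export (0.95, SE 0.25), NHERF1, an apical scaffold protein (0.91, SE 0.24), and ZNF117 (1.09, SE 0.29), all at an adjusted p of 0.518. RPL7AP10 is a pseudogene name, and its signal is uncertain for that reason. limma called 0 of 3611 probes, and 333 had an unadjusted p below 0.05.

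At dose 10 the proteasome list (median 0.52, 19 of 21 genes higher) and the respiratory chain list (median 0.54, 24 of 26 higher) were shifted upward, each with an adjusted p of 0.00122. Both had adjusted p = 0.925 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. The members with the lowest p were PSMA6 (1.18, SE 0.43) and PSMB5 (0.89, SE 0.39) of the proteasome, and SDHC (1.05, SE 0.43) and ATP5PD (0.89, SE 0.38) of the respiratory chain. 2 of the 4 dose 10 arrays are among those that stood apart. Without the 3 arrays the lists had adjusted p = 0.430 and 0.753, and without dose 10 replicate 2 alone 0.0748 and 0.120. The number of shifted lists was 0 without dose 10 replicate 2 and 5 without dose 10 replicate 3 or either dose 1000 array. Over the alternatives other than the estimated correlation the adjusted p of both lists ranged from 0.000114 to 0.788. Among the dose 1000 calls, 59.5% of probes had the same sign at dose 10, and 49.3% with different controls. The simulations gave 79.1%, but among probes picked from noise alone, so this is not the share to expect of the calls.

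Against dose 10, dose 1000 differed in 549 probes, 130 higher and 419 lower. The largest rises were MICAL2 (3.23, SE 0.67), JUNB (2.68, SE 0.25), SLC6A10P (2.19, SE 0.57), CYP1A1 (2.10, SE 0.34) and SLC6A8 (2.05, SE 0.57). ZNF43 (-4.12, SE 0.46), ZNF117 (-4.08, SE 0.36), ZNF93 (-4.06, SE 0.49), ZNF257 (-3.71, SE 0.37) and HSP90AA1 (-3.47, SE 0.65) fell most. With each array centred the split was 272 higher and 312 lower of 584. The count was 128 when only these arrays were fitted, where MICAL2, SLC6A10P, CYP1A1, SLC6A8 and HSP90AA1 did not pass, and 109, 32 higher and 77 lower, without dose 1000 replicate 1, where SLC6A10P, SLC6A8 and HSP90AA1 did not pass. Without dose 10 replicate 4 the split was 83 higher and 293 lower. SLC6A8 did not pass without dose 1000 replicate 2 or dose 10 replicates 1 or 3 either.

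Against dose 100, dose 1000 differed in 380 probes, 69 higher and 311 lower. MICAL2 (2.81, SE 0.63), SLC6A10P (2.40, SE 0.57), SLC6A8 (2.22, SE 0.57), JUNB (1.63, SE 0.25) and MT2A (1.44, SE 0.23) rose most. ZNF117 (-3.21, SE 0.36), ZNF43 (-3.12, SE 0.46), IPO7 (-3.06, SE 0.56), ZNF93 (-2.96, SE 0.49) and PDCD4 (-2.52, SE 0.36) fell most. With each array centred the split was 177 higher and 252 lower of 429. The count was 5 when only these arrays were fitted, where only ZNF117 and ZNF43 of the 10 passed, 49 without dose 1000 replicate 1 (12 higher, 37 lower), 247 without dose 100 replicate 2 (25 and 222) and 250 without dose 100 replicate 4 (34 and 216). Without dose 100 replicate 1 the split was 41 higher and 281 lower, without dose 100 replicate 3 it was 152 and 279, and without the 3 arrays apart 213 and 334. SLC6A8 did not pass without dose 100 replicate 2 or 4 or either dose 1000 array, nor did SLC6A10P, MT2A and IPO7 without dose 1000 replicate 1, or MICAL2 without dose 1000 replicate 2. Between dose 100 and dose 10, limma called 0 of 3611 probes, with 212 at an unadjusted p below 0.05 and 2 called without dose 10 replicate 1. CYP1A1, at 1.10 (SE 0.34) between dose 1000 and dose 100, had adjusted p = 0.0554.

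Between dose 100 and dose 10, 5 lists passed. The NF-kB list (adjusted p = 0.00114) and the immediate-early list (0.00128) were higher at dose 100, and the proteasome (0.000102), respiratory chain (0.000914) and heat shock (0.00773) lists were lower. With an estimated correlation their adjusted p was 0.359, 0.0849, 0.817, 0.898 and 0.707. The respiratory chain list had adjusted p = 0.0904 without dose 10 replicate 2, and without the 3 arrays that stood apart it had 0.417 and the heat shock list 0.101. Between dose 1000 and dose 10 the NF-kB (0.00270) and immediate-early (0.00165) lists were higher and the heat shock list (0.00468) was lower, with adjusted p = 0.411, 0.0534 and 0.839 with an estimated correlation. No list passed between dose 1000 and dose 100.

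A slope over the ordered doses was called for 56 probes, 31 rising and 25 falling. CYP1A1 had the steepest rise, by 0.86 on the log2 scale per dose step (SE 0.10, adjusted p = 0.00131), ahead of JUNB (0.78, SE 0.13), TNFAIP3 (0.72, SE 0.16), NFKBIA (0.70, SE 0.10) and DGAT1 (0.67, SE 0.13). The steepest falls were NBPF12 (-0.74, SE 0.16), NBPF10 (-0.70, SE 0.14), SKP2, the F-box protein that targets p27 (-0.56, SE 0.12), YAP1, the Hippo pathway coactivator (-0.55, SE 0.12), and LBR, the lamin B receptor (-0.46, SE 0.10). With each array centred, 34 rose and 44 fell of 78. The slope rests on dose 1000: without its 2 arrays 1 probe was called, and without either alone also 1, and of the 10 named genes only CYP1A1 then passed. Without control replicates 1, 2 or 4 the counts were 31, 8 and 7, and without dose 10 replicate 1 and dose 100 replicates 2, 3 and 4 they were 18, 21, 105 and 97. Of these, 12, 11, 36 and 41 rose, and 18, 5 and 5 for the controls. Without control replicate 3 the split was 17 rising and 22 falling, and without dose 10 replicate 3 it was 19 and 19. Without control replicate 2 or 4 only CYP1A1, JUNB and NFKBIA of the 10 passed. TNFAIP3 did not pass without control replicates 1 or 3, dose 10 replicate 1 or dose 100 replicates 1 or 2 either. Nor did YAP1 without control replicates 1 or 3, dose 10 replicate 1 or dose 100 replicate 2, LBR without control replicate 1, dose 10 replicate 1 or dose 100 replicates 1 or 2, NBPF12 without control replicate 3 or dose 10 replicate 1, and SKP2 without dose 10 replicate 1.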

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

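The tests of a batch that crosses doses, of the dose of the bacterium, of array scaling and of array processing measured by the repeated spots were chosen after the result was seen, as were the fits with the shift of these spots as a covariate and without the 3 arrays.

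Dose 10 replicates 2 and 4 and dose 100 replicate 3 stood apart from the other arrays of their doses. Wrongly labelled dose 1000 arrays stay open. The dose 1000 calls shifted in the called direction by at most 0.16 in the 3 arrays, against 1.01 and 1.22 in the dose 1000 arrays. These calls were picked on the dose 1000 arrays, with a spread that took in the 3 arrays under their labels. Probes on which the 3 moved like dose 1000 were thus less likely to be called, so the test decides nothing. Over all gene probes dose 1000 replicate 2 correlated with the 3 at 0.692 to 0.743, about as with dose 1000 replicate 1 (0.725). With the other 5 arrays of doses 10 and 100 it correlated at 0.623 to 0.765, so this likeness is not particular to the 3. A batch of arrays or samples that crosses doses may account for them: the dose 100 array correlated with the dose 10 arrays of the 3 at 0.863 or more, while the highest correlation of any of the 3 with another array of its own dose was 0.798. The labels give no batch. The labelled dose is argued against, since it is the same on both sides of the split. Within dose 10 the repeated spots lay at -1.60 and -1.74, against -0.16 and -0.30 in the other arrays. Within dose 100 they lay at -1.79, against -0.14 to -0.10. The other 5 arrays of the same doses correlated with each control at 0.784 or more, above the highest value of the 3, 0.751. It was by such shifts and correlations that the 3 stood apart, so they show the split but not its cause.

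At dose 1000, falls outnumbered rises. Dose 1000 replicate 1 is argued against as the whole cause, since without it 33.8% of calls were rises, against 31.4% with all arrays. On replicate 1 as the only dose 1000 array, 19.6% were rises, so it may add to the imbalance. Array scaling could account for part of the imbalance: with each array centred, 43.5% were rises, though falls still outnumbered rises. It stays open how much of the imbalance is the scale of the values, and the dose itself remains among the open explanations.

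At dose 1000, 7 of 10 immediate-early genes and 5 of 7 NF-kB genes were higher, 4 and 5 of them called, and both lists passed there and at dose 100; with an estimated correlation the adjusted p was 0.0484 and 0.604 at dose 1000 and 0.0518 and 0.454 at dose 100. Array processing as the repeated spots measure it stays open. The median over the 17 genes was 1.23 with the shift of the spots as a covariate and 1.17 without. The shifts at dose 1000, 0.30 and -0.61, lay on either side of the controls (-0.03 to 0.02). The covariate could therefore move this median little, so the test decides nothing. Chance values of the shared controls stay open. The share of these genes higher at both doses was 61.8% with different controls for each dose (58.8% to 64.7% over 6 ways) and 58.8% with all 4, but the lists were picked from their calls against these same 4 controls and no share without a change was set beside it, so the bound written for this test decides nothing. Batches that follow dose 1000 could not be tested, since no label gives one.

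Of 222 groups of 4 arrays, 19 had 1 array far from the other 3, where about 11.1 would by chance. The rule finds only a lone array, so dose 10 replicates 2 and 4, which stood apart together, could mask each other. Among the arrays found, dose 100 replicate 3 was the most frequent. Its repeated spots lay at -1.79 (others -0.14 to -0.10) and its median over gene probes at 0.43 (others 0.02 to 0.07). It stood at 1.51 for IPO7 (others -0.31 to -0.14), 0.46 for HSP90AA1 (-1.10 to -0.90), 0.49 for DNAJA1 (-0.69 to -0.49) and 0.81 for IER3 (-0.26 to -0.10). It also stood at 0.55 for PDHA1 (-0.36 to -0.30), 0.89 for PSMB5 (-0.52 to -0.39), 0.76 for SDHC (-0.78 to -0.54) and 1.60 for SLC40A1 (2.37 to 2.50).

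The other arrays far from their group were spread over genes. Dose 100 replicate 4 stood at 0.38 for ZNF117 (others 0.80 to 0.86) and 0.77 for GPX4 (1.64 to 1.81), dose 100 replicate 1 at -0.61 for SKP2 (0.02 to 0.14) and dose 10 replicate 4 at 1.00 for PDCD4 (1.52 to 1.61). Among the controls, replicate 4 stood at 2.18 for CYP1A1 (2.11 to 2.12), replicate 3 at -1.39 for MDK (-1.76 to -1.74) and 0.13 for HSPA8 (0.04 to 0.05), replicate 1 at 0.71 for DNAJB11 (0.02 to 0.12) and replicate 2 at 0.59 for FN1 (0.03 to 0.11).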

How the results depend on the processing

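The fits with the repeated spots kept, without the 3 arrays that stand apart, with these as a batch term, with the spots' shift as a covariate and with named probes only were chosen after the data were seen. Over the alternatives, 246 named values were recomputed 7350 times: 6942 kept their side of the adjusted p threshold, 352 lost a call and 56 gained one. Of those called in the main fit or the alternative, 0 reversed. Changes of sign in values called in neither were not counted, and the fold change floor did not enter these counts. The cause of the moves below was not tested, except where fewer probes, genes or arrays enter. The number of arrays, and 2 at dose 1000, limit all counts; signal over background was not analysed here.

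Leaving out 1 array at a time gave 0 to 0 genes at dose 10, 0 to 1 at dose 100 and 133 to 606 at dose 1000 against the control. It gave 0 to 2 for dose 100 against dose 10, 49 to 493 for dose 1000 against dose 100, 109 to 645 for dose 1000 against dose 10 and 1 to 105 for the slope. Lists ranged from 0 to 5 at dose 10, 1 to 5 at dose 100 and 2 to 4 at dose 1000.

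With the replicate number as a block, dose 1000 gave 325 against the control (100 higher, 225 lower), 204 against dose 100 and 322 against dose 10. The slope gave 3, and lists numbered 4 at dose 10 and 4 at dose 100. After the group mean of each probe was taken out, 5 of 18 same-number pairs correlated above 0.1 (-0.460 to 0.489). No pairs of different numbers were set beside these, so whether the numbers pair the arrays stays open. Array weights gave 51 at dose 100, 264 at dose 1000, 1 for dose 100 against dose 10, and 145 and 191 for dose 1000 against dose 100 and 10. Fitting only the arrays compared gave 4 at dose 100, 5 and 128 for dose 1000 against dose 100 and 10, and 4 lists at dose 10 and 4 at dose 100. Lists at dose 100 numbered 4 after centring, 0 with only probes on all 14 arrays, 1 with 1 value per group and 5 with 1 probe per gene. Those at dose 1000 numbered 0 with only probes on all 14 arrays, and those at dose 10 were 4 without the probes of smallest variance. An estimated correlation left 0, 0 and 1 list at the rising doses.

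With a floor of a 1.5-fold change per dose step, the slope was called for 10 probes. It was called for 90 after quantile normalization, 1 without dose 1000 and 18 without the probes of smallest variance. It was called for 663 with dose as a linear number (199 higher, 464 lower) and for 109 in treated arrays only (20 higher, 89 lower). After quantile normalization 203 were higher and 318 lower of 521 at dose 1000, 125 and 218 of 343 against dose 100, 229 and 296 of 525 against dose 10, and 29 and 61 for the slope. Scaling to 1 median absolute log ratio gave 30 higher and 52 lower of 82 for the slope.

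Keeping the repeated spots gave 350 at dose 1000 against the control (91 higher, 259 lower) and 399 against dose 10 (89 and 310). It gave 249 for dose 1000 against dose 100 and 14 for the slope. Without the 3 arrays there were 1 at dose 100, 739 at dose 1000, 112 for the slope and 0 lists at dose 10. With them as a batch term there were 2, 758, 618 for dose 1000 against dose 100, 183 for the slope and 0 lists at dose 10. With the covariate there were 2, 869, 699, 356, 0 lists at dose 10 and 6 at dose 100.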

Other observations

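The genes in the next paragraph were chosen after their values were seen, and the trend's tie to the repeated spots was looked at after its splits were counted.

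Genes measured on both dose 1000 arrays and on no control numbered 6, beside 1 unnamed probe. NR1D1, a nuclear receptor of the circadian clock, stood at 3.40 and 3.24 at dose 1000, at 1.69, 1.23, 1.25 and 1.35 at dose 100 and at -0.03 on 1 dose 10 array. CDKN1A, the inhibitor p21 of cyclin-dependent kinases, stood at 4.18 and 4.28 at dose 1000, at 3.32 and 2.86 on 2 dose 100 arrays and at 4.11 and 2.96 on 2 dose 10 arrays. The others were PPIL4, MXI1, PPP4R4 and KCNV1. In the other direction, 342 probes, 300 of them named, had a value on all controls and on neither dose 1000 array. A missing value is not a low one, so these are values without a test.

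That zinc finger genes fall together at dose 1000 was a hypothesis raised by the 4 among the largest falls. Over 37 measured genes of this name, 7 fell and 1 rose, with a median of 0.09 and p = 0.863 with an estimated correlation. The probes of the 4 genes correlated at 0.961 to 0.990 across arrays, and without these genes the p was 0.366 over 33.

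Other splits of the arrays were counted. At dose 10 and at dose 100, with 0 genes called, all 35 splits necessarily gave as many, the highest other being 0, so these counts say nothing of chance. For the lists, 13 of 35 splits gave as many as the 2 at dose 10, and 5 of 35 as many as the 2 at dose 100, each with a highest other of 4, so chance is not excluded there. Between dose 100 and dose 10, all 35 splits likewise gave at least the 0 of the real one. The highest other, 182, set all 3 arrays that stand apart on 1 side, which points to a structure of the arrays, but of the 5 splits that do so the others gave 22, 1, 0 and 0, and the remaining 30 gave 0. At dose 1000, 1 of 15 splits gave 484, the real one, with a highest other of 0, and the splits are too few for a share under 0.05. For the slope, 2 of 100 drawn splits, the real one included, gave as many as 56. As the slope rests on the 2 dose 1000 arrays, this share can reflect a difference of these alone. Chance is therefore not excluded for a trend over the doses. The highest other, 160, points to a structure of the arrays. Its doses correlated with the shift of the repeated spots at 0.677, but draws at 0.601, 0.521 and -0.584 gave 0, so its cause stays open.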
